A study of Mus musculus with 2 samples.

How the data were processed

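DNA methylation of intracisternal A particle (IAP) long terminal repeats (LTRs) was measured in 2 mouse cell lines, with 1 library per line: AB2.2, an embryonic stem (ES) cell line of strain 129, and Neuro2A, a brain neuroblastoma line of strain A albino. Per the labels' protocols, genomic DNA was sonicated, ligated to an adaptor, treated with bisulfite, amplified by a PCR that enriches the junctions of IAP LTRs with their flanking genome, and size-selected on agarose. The method is named HT-TREBS (high-throughput targeted repeat element bisulfite sequencing) in the series' design text, which also names the Ion Torrent PGM as the sequencer. Bisulfite turns unmethylated cytosine into a base read as T, so incomplete conversion raises a measured methylation level.

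The deposited value is a score per LTR that equals the methylation level as a fraction multiplied by 1000, per the file headers, and it was divided by 10 here to give percent. The genome build is mm9, per the file headers. Bowtie2 is named in the submitters' processing notes, without its role or version. The methylation caller, the read filters, the rule by which loci were kept and the treatment of reads that fit several copies are not given in the sources used here. Each library listed a level for the same 4799 loci, and none was missing. The values carry no read number, so the sequencing depth behind each level is unknown, and no interval for counting error and no test on reads could be given. The planned minimum of 10 reads per locus (with 5 and 20 as alternatives), the weighting by coverage and Fisher's exact test per locus were therefore not applied.

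Each locus was placed by the coordinates within its name, written here 1-based on mm9, with the subfamily and strand that the name gives. For 1 locus of the ES library the position columns disagreed with the name, and the name was used. No annotation of mm9 was used. The gene table at hand describes a later assembly, so the comparisons planned by gene body, by transcription start and by gene lists (imprinted, pluripotency, neuronal, silencing and gene family lists) were not made, and loci are reported by position and subfamily.

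With 1 library per cell line there is no replicate, and no p-value is given for any difference between the lines. SDs over loci describe how loci vary and are not experimental errors. The exact (Clopper-Pearson) 95% intervals on shares treat loci as draws and cover neither sequencing error nor variation between cultures. Levels under 20% were called low, levels of 80% or above high, and levels between them intermediate. A difference of 20 percentage points or more between the libraries was counted per direction. A group of at least 20 loci was set against 10000 random sets of as many loci by the percentile of its median difference, and neighbouring loci were compared with shuffles of the values within chromosomes. Both describe these libraries.

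The named loci follow a rule fixed in advance: the 8 with the largest excess in each library and the 5 with the lowest mean of both, plus groups whose median lies at or under percentile 1 or at or over percentile 99. Individual loci named outside the rule, such as members of the high-to-low list, were chosen after their values were seen. Alternatives fixed before the data were examined were other class limits (10 and 90%, 30 and 70%), other difference limits (10 and 40 points), leaving out loci at exactly 0, autosomes only, 1 locus per 100 kb, centring each library on its median, means in place of medians, and neighbours within 100 kb or 5 Mb. Using every locus measured in each library, also planned, gives the same set of loci and so changes nothing. LTR pairs, random sets matched on the ES level (by its deciles), runs of consecutive loci with the chromosomes joined end to end (every start whose run holds no locus of the chromosome compared), shuffles of windows, and values relative to subfamily and LTR position were added after the data were seen. Sets matched on the mean of both lines were also drawn. They placed the IAPLTR1 group above the IAPLTR2 group in percentile, the reverse of the sets matched on the ES level. That mean contains the Neuro2A level, whose wider spread ties a low mean to a large difference. The ES level is itself a term of the difference, so matching on it is not free of such a tie either. Neither match decides between the groups. An LTR pair is a couple of consecutive loci of one subfamily and strand, 1 to 8 kb apart; the upstream member is called the candidate 5′ LTR and the other the candidate 3′ LTR of one provirus.

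The scripts were tested on simulated levels for the same 4799 loci. Every locus planted with a difference of 30 or of 50 points was recovered, and no unplanted locus passed the limit. The planted differences were larger than the limit, so this outcome checks only that the scripts count differences correctly. It does not measure how reliable the calls are in the real libraries, whose sequencing depth is unknown. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.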

Results

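IAPs are a family of mouse endogenous retroviruses whose LTRs hold the element's promoter, and their copies are commonly silenced by CpG methylation. The series asked how methylation of individual IAP LTRs differs between cell types. Levels from AB2.2 ES cells and Neuro2A neuroblastoma cells, 1 library each, are compared here, and the somatic cells that the design also names were not analysed here. Both libraries gave a level for 4799 LTR loci with a median length of 366 bp. By name, 912 loci were IAPLTR1_Mm, 1234 IAPLTR1a_Mm, 1391 IAPLTR2_Mm, 672 IAPLTR2a and 576 IAPLTR2b, with 10 IAPLTR4, 3 IAPLTR4_I and 1 IAPLTR3 copies. The depth behind each level is unknown.

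IAP LTRs were highly methylated in both lines, and less so in Neuro2A cells. The mean level was 84.6% in ES cells (SD over loci 8.76) and 76.0% in Neuro2A cells (SD over loci 16.8). The median was 86.7% in ES cells against 80.6% in Neuro2A cells. The level was higher in the ES library at 3907 loci, higher in the Neuro2A library at 882 and equal at 10. ES cells were thus the higher at 81.4% of loci (95% interval over loci 80.3 to 82.5), and the median difference was 6.1 percentage points. Without a second culture of either line, this difference has no replicate check. The interquartile range was 80.5 to 91.2% in ES cells and 69.3 to 87.6% in Neuro2A cells.

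ES cells had 3689 loci at 80% or above (76.9%, interval 75.7 to 78.1), against 2465 (51.4%, interval 49.9 to 52.8) in Neuro2A cells. Loci under 20% were rare in each line. They numbered 2 in ES cells and 47 in Neuro2A cells, or 0.98% of loci there (interval 0.72 to 1.30). Of the loci high in ES cells, 1407 (38.1%) were intermediate in Neuro2A cells, while 203 loci went from intermediate in ES cells to high in Neuro2A cells. A single locus was low in both lines. Independent lists of 2 and 47 loci would share 0.020 loci, and 1.94% of 10000 random relabellings shared at least 1. The shared locus was listed at exactly 0 in each library, and without loci at 0 no locus was low in both.

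**Figure D1:**
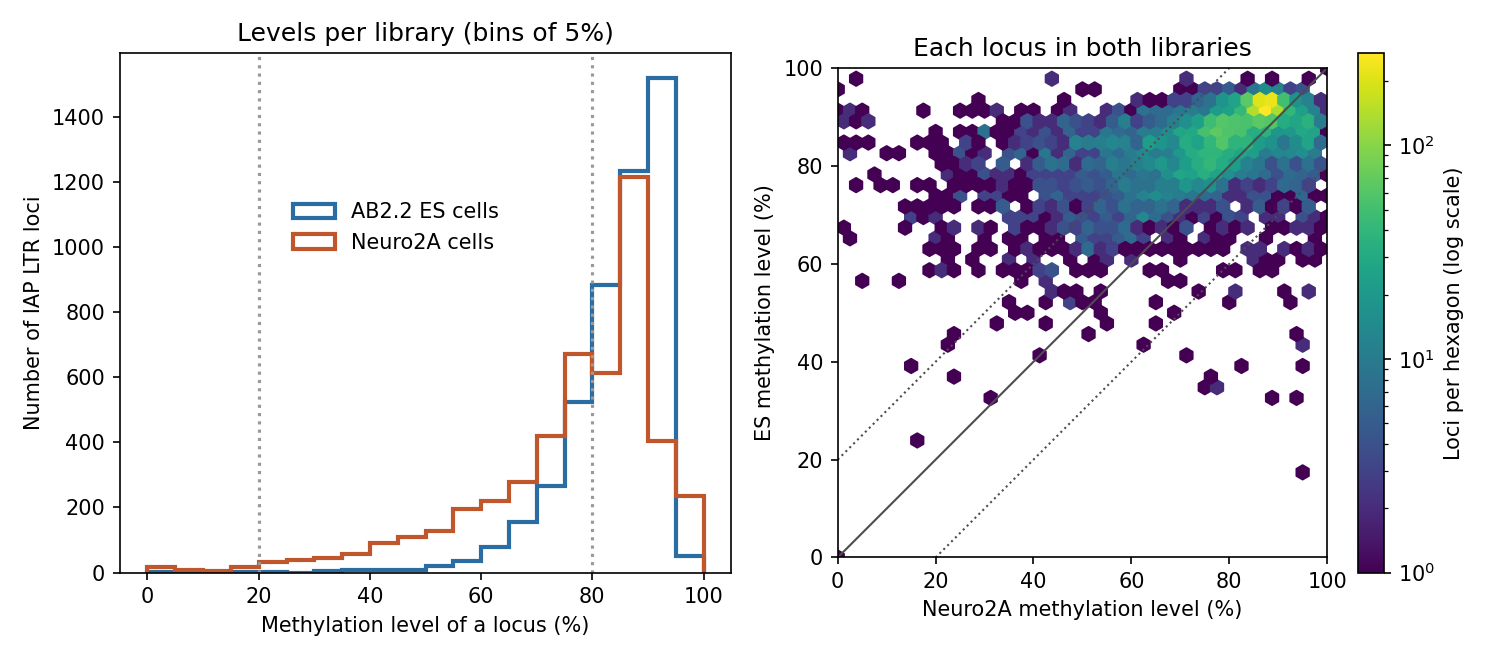
Left, number of IAP LTR loci by methylation level in percent, in bins of 5%, for the ES (blue) and Neuro2A (orange) libraries, with dotted lines at 20 and 80%. Right, density of the 4799 loci by Neuro2A level (x, %) and ES level (y, %), with the solid line at equality and dotted lines at a difference of 20 points; most of the density lies above equality, and 717 loci lie on or above the upper dotted line against 76 on or below the lower one.

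At 717 loci (14.9%, interval 13.94 to 15.98) the ES level exceeded the Neuro2A level by 20 points or more, and at 76 loci (1.58%, interval 1.25 to 1.98) the reverse held. ES cells were therefore the higher line at 90.4% of these loci. After each library was centred on its own median, which removes a shift of 6.1 points, the counts were 500 and 153, and the share was 76.6%. Levels in the lines were related across loci, with Pearson's r of 0.48 and Spearman's rho of 0.54. These coefficients describe loci of 2 libraries, and loci are not independent replicates.

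The 8 loci with the largest excess in ES cells were all IAPLTR1_Mm or IAPLTR1a_Mm copies at 88.7% or more in ES cells and at 4.0% or less in Neuro2A cells. An IAPLTR1_Mm copy on chromosome 7 (144606702 to 144607081, plus strand) was at 96.4% in ES cells and was listed at 0.0% in Neuro2A cells. An IAPLTR1a_Mm copy on chromosome 16 (20579805 to 20580163, minus strand) had 98.6% and 4.0%. The IAPLTR1a_Mm copy on chromosome 4 (48696531 to 48696869, minus strand) had 91.8% and 0.4%, and the IAPLTR1_Mm copy on chromosome 11 (51483384 to 51483720, minus strand) had 92.1% and 2.3%. On chromosome 12, IAPLTR1a_Mm copies at 86748791 to 86749127 and at 66134957 to 66135294, both on the minus strand, were at 90.4 and 88.7% in ES cells and at 1.6 and 1.5% in Neuro2A cells. The remaining copies were an IAPLTR1a_Mm on chromosome 11 (106158561 to 106158897, minus strand) at 88.7% and 0.9% and an IAPLTR1_Mm on chromosome 7 (25368799 to 25369149, minus strand) at 89.3% and 3.4%.

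In all, 21 loci were high in ES cells and low in Neuro2A cells. Of these, 15 were IAPLTR1_Mm or IAPLTR1a_Mm, subfamilies that made up 44.7% of all loci, and 17 lay on the minus strand, as did 51.1% of all loci. By position, 11 of the 21 were candidate 5′ LTRs of a same-strand LTR pair, a class that held 18.9% of all loci. A neighbouring couple on chromosome 8, IAPLTR1_Mm copies at 13715388 to 13715757 (minus strand) and 13719305 to 13719641 (plus strand), lay 3547 bp apart. Their levels were 83.8% and 81.6% in ES cells and 0.8% and 2.7% in Neuro2A cells. The lines differ in strain. Whether each locus named here and in the other lists is present with the same sequence in both lines was not checked.

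Of the 76 loci higher in Neuro2A cells by 20 points or more, 43 were IAPLTR2_Mm, 15 IAPLTR2a, 14 IAPLTR2b and 4 IAPLTR1_Mm copies. Just 1 locus was high in Neuro2A cells and low in ES cells, an IAPLTR2b copy on chromosome 14 (12148594 to 12148809, plus strand) at 94.4% and 18.4%, respectively. The next in size was an IAPLTR1_Mm copy on chromosome 9 (3466120 to 3466472, minus strand), at 93.7% in Neuro2A cells and 33.7% in ES cells. IAPLTR2a copies on chromosome 8 (82133248 to 82133637, minus strand) and chromosome 16 (96232553 to 96232942, plus strand) had 90% and 95.9% in Neuro2A cells against 32.7% and 43.8% in ES cells. An IAPLTR2b copy on chromosome 3 (152918593 to 152918924, plus strand) had 95.9% against 39.3%. The IAPLTR2_Mm copies on chromosome 7 (6037727 to 6038171, minus strand), chromosome 12 (103873153 to 103873626, plus strand) and chromosome 5 (115149485 to 115149936, minus strand) had Neuro2A levels of 94.7%, 94.8% and 82.3% and ES levels of 44.4%, 45.2% and 38.0%.

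The lowest mean over both lines belonged to an IAPLTR4 copy on chromosome 5 (146512964 to 146513306, minus strand), which was listed at 0.0% in each. It was followed by an IAPLTR2_Mm copy on chromosome 6 (37414146 to 37414607, plus strand) at 23.5% in ES cells and 16.8% in Neuro2A cells, and by an IAPLTR1_Mm copy on chromosome 10 (121807695 to 121808048, minus strand) at 38.4% and 14.2%. An IAPLTR2b copy on chromosome 3 (44333804 to 44333933, plus strand) had 36.9% and 22.8%, and an IAPLTR2a copy on chromosome 2 (111437078 to 111437474, minus strand) had 56.0% and 4.8%.

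Subfamilies differed in level, with the IAPLTR1 group above the IAPLTR2 group in both lines. In ES cells the mean was 90.2% for IAPLTR1_Mm (SD over loci 5.46) and 88.5% for IAPLTR1a_Mm (5.47), against 80.9% for IAPLTR2_Mm (8.87), 81.1% for IAPLTR2a (8.60) and 80.6% for IAPLTR2b (9.30). In Neuro2A cells the means were 84.1% (11.3), 82.1% (12.1), 69.9% (18.3), 71.7% (18.02) and 70.9% (16.4), in that order. The median difference between the lines was 5.0 points for IAPLTR1_Mm and 4.9 for IAPLTR1a_Mm, below all 10000 random sets of as many loci, and -1.1 and -1.2 points once each library was centred on its median. It was 8.7 points for IAPLTR2_Mm, 8.1 for IAPLTR2a and 8.7 for IAPLTR2b, above all random sets. On means, IAPLTR2_Mm stayed above all sets, while IAPLTR2a (9.42 points, percentile 94.35) and IAPLTR2b (9.68 points, percentile 97.06) lay within the central 95% of them. A difference of 20 points or more in favour of ES cells was found at 24.7% of IAPLTR2_Mm, 21.9% of IAPLTR2a and 19.4% of IAPLTR2b loci, against 4.28% of IAPLTR1_Mm and 5.43% of IAPLTR1a_Mm loci. At candidate 5′ LTRs the IAPLTR1_Mm and IAPLTR1a_Mm shares were 36 of 181 (19.9%) and 49 of 314 (15.6%). They were 0 of 181 and 2 of 314 at candidate 3′ LTRs, and 3 of 550 and 16 of 606 at unpaired loci. Candidate 5′ LTRs of IAPLTR2_Mm, IAPLTR2a and IAPLTR2b had 37.7, 35.0 and 30.3%. The spread of levels also varied with position in a copy: over 906 same-strand LTR pairs, the Neuro2A SD was 19.6 at candidate 5′ LTRs and 11.4 at candidate 3′ LTRs. The Neuro2A medians were close, at 79.6% and 79.95%.

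As a ratio, the gaps did not separate the groups. The mean unmethylated share was 1.63 times as high in Neuro2A as in ES cells for IAPLTR1_Mm, 1.56 times for IAPLTR1a_Mm, 1.58 times for IAPLTR2_Mm and 1.498 times for both IAPLTR2a and IAPLTR2b. Against random sets matched on the ES level, the median difference in points of IAPLTR1a_Mm lay below all sets and that of IAPLTR1_Mm at percentile 0.075, while IAPLTR2_Mm and IAPLTR2b lay above all sets and IAPLTR2a at percentile 99.96. Sets matched on the mean of both lines gave the reverse order. There IAPLTR1_Mm stood at percentile 100, IAPLTR1a_Mm at 98.7, IAPLTR2_Mm at 26.7, IAPLTR2a at 27.1 and IAPLTR2b at 28.85. Each matching level shares a term with the difference, so neither match decides between the groups. The 10 IAPLTR4 loci had the lowest levels of the LTR subfamilies with more than 1 copy, with a mean of 62.1% in ES cells (SD 26.7) and 33.4% in Neuro2A cells (SD 24.4), and 7 of them exceeded a difference of 20 points.

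**Figure D2:**
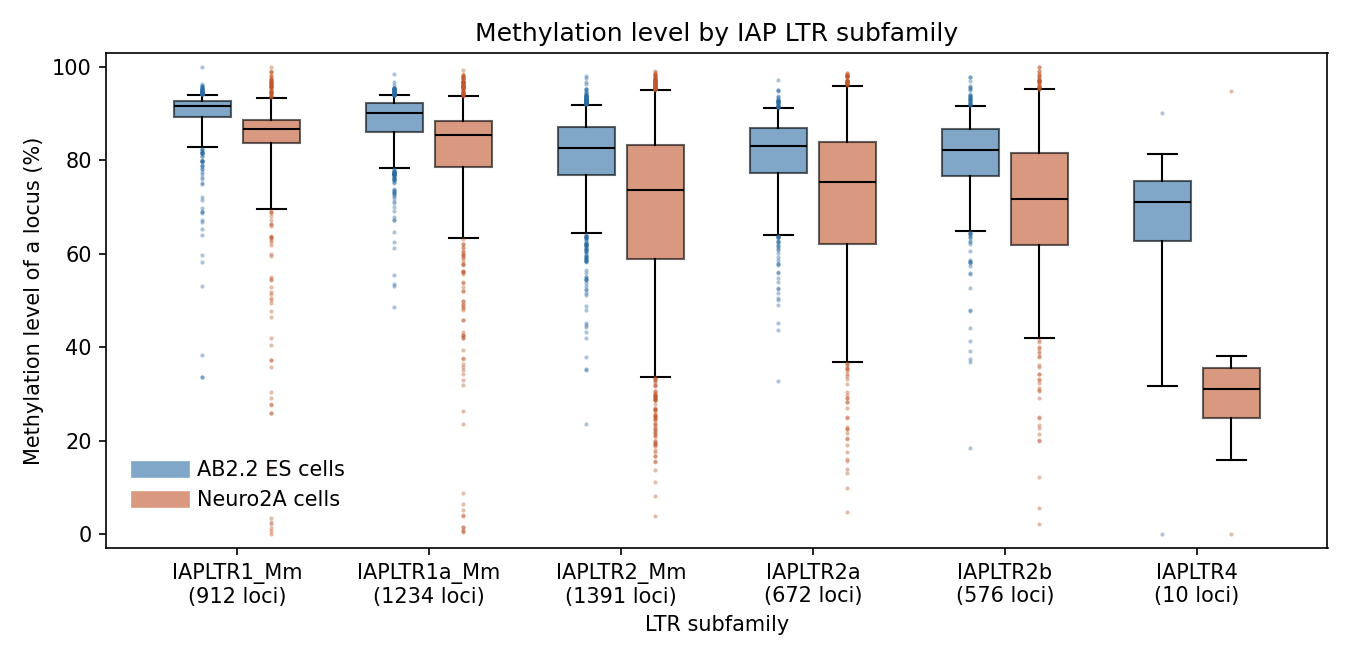
Methylation level per locus (%) by LTR subfamily in ES (blue) and Neuro2A (orange) cells. Boxes give the quartiles and the median, whiskers the percentiles 5 and 95 and points the loci outside them; IAPLTR1 copies lie higher and closer together than IAPLTR2 copies in both lines, and IAPLTR4 medians are 71.1% in ES and 31.1% in Neuro2A cells.

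By chromosome, the X had the largest median difference and chromosome 10 the smallest among chromosomes with at least 20 loci. On the X, 418 loci had a median difference of 7.9 points, above all random sets of that size, and 20.8% of them (interval 17.02 to 25.03) were lower in Neuro2A cells by 20 points or more, against 14.5% of autosomal loci (interval 13.5 to 15.6). The median ES level was 86.4% on the X and 86.8% on autosomes, and the median Neuro2A level was 77.7% and 81.0%. Within subfamilies, the X had the larger median difference for IAPLTR2_Mm (11.7 against 8.5 points), IAPLTR2b (10.9 against 8.35), IAPLTR1a_Mm (6.35 against 4.7) and IAPLTR2a (8.7 against 8.1), and the smaller for IAPLTR1_Mm (4.8 against 5.0). On chromosome 10, 253 loci had a median difference of 4.2 points, below all random sets and at -1.9 points after centring, and 12.6% of them exceeded 20 points. Matching on the ES level left the X above and chromosome 10 below all sets. Random sets of single loci ignore that neighbouring loci resemble each other, and runs of as many consecutive loci varied more. The X lay above every run that held none of its loci (medians 4.6 to 7.15 points) and chromosome 10 below every such run (4.9 to 10.2 points). These runs overlap heavily, so few are independent, and both chromosomes had been picked as the extremes. Among all runs, with those that hold their own loci, the X stood at percentile 97.6 and chromosome 10 at 0.96. Chromosome 8, at 5.0 points, was just under the central 95% of random sets (percentile 2.13) and inside the range of runs without its loci (3.7 to 10.35 points). On means, the X (11.4 points) again lay above such runs (6.06 to 10.4 points). Chromosome 10 (6.39 points, percentile 0.81 of random sets) and chromosome 19, which had the smallest mean difference of these chromosomes (5.02 points, percentile 0.88), lay inside their ranges (5.72 to 15.2 and 2.14 to 17.2 points). The loci placed on unassigned Y sequence, 37 in number, had a median difference of 5.4 points, inside the range of random sets (3.8 to 9.2).

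**Figure D3:**
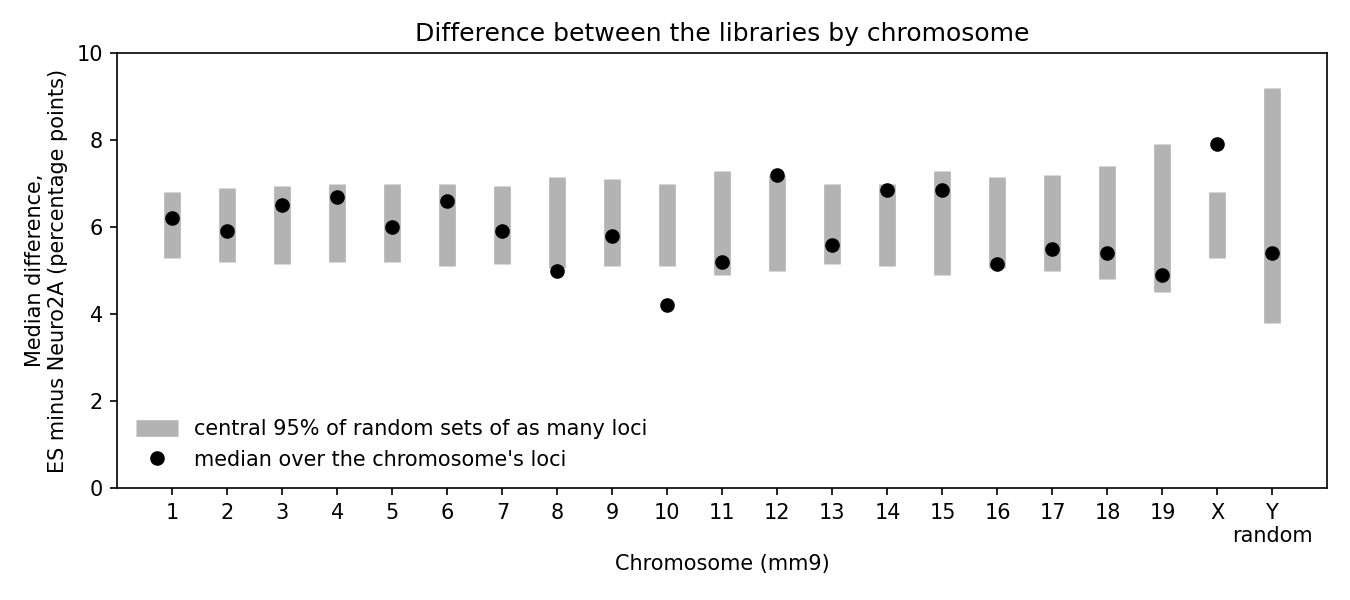
Median difference in methylation level, ES minus Neuro2A, in percentage points (y) for each mm9 chromosome with at least 20 loci (x). Points are medians over loci and grey bars the central 95% of 10000 random sets of as many loci; the X (7.9 points) lies above its bar, and chromosomes 10 (4.2 points) and 8 (5.0 points) lie below theirs.

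Loci close to one another had similar differences. Over 2950 pairs of nearest neighbours within 1 Mb, Spearman's rho of the difference was 0.20 and Pearson's r 0.17, while the highest rho among 10000 shuffles within chromosomes was 0.073. The same neighbours had a rho of 0.23 for the Neuro2A level and 0.087 for the ES level, each above all 1000 shuffles (highest 0.058 and 0.053). For neighbours 10 kb to 1 Mb apart, and relative to the median of their subfamily and LTR position, the rho was 0.13 for the Neuro2A level and -0.0093 for the ES level.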

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

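No paired analysis was possible because each cell line has 1 library. Under the alternatives, 62 values kept their direction and stayed within their interval over loci or, for counts, within 1.5 times, while 36 moved further and 3 were reversed. Values without candidate 3′ LTRs and on values relative to subfamily and LTR position were chosen after the data were seen. With limits of 10 and 90%, high loci made up 32.7% in ES cells and 13.3% in Neuro2A cells, low loci 0.50% in Neuro2A cells, and 6 loci were high in ES and low in Neuro2A cells with 0 the other way. With limits of 30 and 70%, these were 93.3%, 74.1%, 2.44% and 83 loci, with 2 loci low in both lines. A limit of 10 points gave 1548 loci higher in ES and 275 higher in Neuro2A cells, and a limit of 40 points gave 203 and 14. Centring each library on its median raised the loci higher in Neuro2A cells from 76 to 153 and set the median differences to -1.1 points for IAPLTR1_Mm, -1.2 for IAPLTR1a_Mm and -1.9 for chromosome 10, all reversed, and to 2.6 for IAPLTR2_Mm and IAPLTR2b, 2.0 for IAPLTR2a and 1.8 for the X; centring subtracts 6.1 points by construction. Means in place of medians gave 6.12 points for IAPLTR1_Mm, 6.43 for IAPLTR1a_Mm, 11.1 for IAPLTR2_Mm, 9.42 for IAPLTR2a, 9.68 for IAPLTR2b, 6.39 for chromosome 10 and 11.4 for the X. On means, IAPLTR2a (percentile 94.35) and IAPLTR2b (percentile 97.06) no longer lay above all random sets, and chromosome 19 came to percentile 0.88 beside chromosome 10 at 0.81. Runs of consecutive loci without the chromosome's own, which overlap heavily, were chosen after the data were seen. They left the X above every run (highest 7.15 points) and chromosome 10 below every run (lowest 4.9 points) on medians. On means chromosome 10 (6.39 points) lay inside the runs (lowest 5.72). Keeping 1 locus per 100 kb (3241 loci) gave an ES mean of 84.3%, a mean difference of 7.99 points, 75.3% high loci in ES cells, 447 loci higher in ES cells by 20 points and 11 high in ES and low in Neuro2A cells, with fewer loci by construction. Leaving out loci at exactly 0 removed the locus low in both lines, leaving 0. Without candidate 3′ LTRs the ES mean was 84.3%, r was 0.44 and rho 0.49, and 652 loci were higher in ES cells by 20 points. For neighbours within 100 kb the rho was 0.24, and for neighbours 10 kb to 1 Mb away on relative values 0.14. Autosomes only changed none of the values by more than their interval. The loci named by the rule and those high in 1 line and low in the other came to 34. Of these, 31 differed by 20 points or more, and centring took 1 of them under that limit (an IAPLTR1_Mm copy on chromosome 10, from 24.2 to 18.1 points). Most had been picked for large differences, which a shift of 6.1 points cannot bring under the limit. Apart from these constructions the cause of a change was not tested. Depth is unknown, so single loci, above all those listed at 0, have no stated precision.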

Other observations

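All tests in this part were chosen after the result they bear on was seen. Among LTR pairs, the loci hold a contrast in spread between the ends of IAP copies. Consecutive loci of one subfamily and strand that lay 1 to 8 kb apart were taken as candidate 5′ and 3′ LTRs of one provirus, which gave 906 pairs. In Neuro2A cells the candidate 5′ LTRs spread widely (mean 74.7%, SD over loci 19.6) and the candidate 3′ LTRs narrowly (mean 77.9%, SD 11.4), with 53 of the former and 4 of the latter under 40%. The 5′ LTRs also reached higher, with a percentile 95 of 96.5% against 89.9%. Within pairs the median 5′ minus 3′ level was 0.15 points, with the 5′ end lower by 20 points or more in 131 pairs and the 3′ end in 63. The 5′ mean was lower in IAPLTR1_Mm (76.9 against 85.9%), IAPLTR1a_Mm (79.9 against 85.1%) and, barely, IAPLTR2_Mm (68.5 against 69.0%). It was higher in IAPLTR2a (70.2 against 68.9%) and IAPLTR2b (72.9 against 68.1%). The contrast was sharpest in IAPLTR1_Mm, where the Neuro2A SD was 21.9 at the 5′ and 4.72 at the 3′ end over 181 pairs. In ES cells the SDs over all pairs were 6.91 and 7.60, but IAPLTR1_Mm showed a contrast there too (8.83 and 3.75), as did IAPLTR1a_Mm to a smaller degree (4.11 and 3.24). The IAPLTR2 subfamilies did not (6.86 and 6.88 for IAPLTR2_Mm, 7.17 and 7.28 for IAPLTR2a, 7.21 and 8.17 for IAPLTR2b). A difference of 20 points or more in favour of ES cells was found at 231 of 906 5′ LTRs (25.5%) and 65 of 906 3′ LTRs (7.17%). Of the 21 loci high in ES and low in Neuro2A cells, 11 were candidate 5′ LTRs, and their 3′ partners stood at 73.5 to 90.9% in Neuro2A cells (median 87.7%). These copies were all IAPLTR1_Mm or IAPLTR1a_Mm, whose 3′ LTRs had Neuro2A medians of 87.0 and 86.8%. Of those 3′ LTRs, 0 of 181 and 0 of 314 were under 40%. High partners were thus usual and not particular to these copies.

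Low Neuro2A levels also gathered in regions. Among 208 windows of 5 Mb with at least 10 loci, the lowest Neuro2A medians relative to subfamily and LTR position were on chromosome 5 from 60 to 65 Mb (-28.9 points, 14 loci), chromosome 2 from 40 to 45 Mb (-23.4 points, 10 loci), chromosome 3 from 45 to 50 Mb (-20.7 points, 12 loci) and the X from 50 to 55 Mb (-19.4 points, 17 loci). The ES medians there were -2.25, -0.80, -7.78 and -0.50 points. The window on chromosome 3 was thus low in ES cells too, where the lowest window of all stood at -9.2 points. Of its 12 loci, 4 were lower in Neuro2A cells by 20 points or more. The window on the X held 12 of the 87 X loci past that limit, so it is not independent of the result for the X above. In 1000 shuffles of the relative levels within chromosomes, the lowest window was as low as the one on chromosome 5 in 0.30%, and the fourth lowest never went under -13.8 points.

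For the narrow spread of candidate 3′ LTRs in Neuro2A cells, a strand effect of the library that favours the left or the right side of a pair was considered. The SD of the 5′ end was larger on both strands, 1.57 times on the plus strand (95% bootstrap interval 1.42 to 1.73) and 1.90 times on the minus strand (1.69 to 2.13), which argues against that form. Of the 21 loci high in ES and low in Neuro2A cells, 17 lay on the minus strand. A strand effect of another form was not tested. Complete averaging of reads over all copies of a subfamily is argued against by the rho of 0.22 between the 5′ and 3′ levels of a pair, above all 10000 shuffles within subfamilies (highest 0.15). Reads partly shared between copies at 3′ LTRs, whose upstream flank is IAP sequence, may still contribute: neighbouring 3′ LTRs had a rho of -0.012 (interval -0.13 to 0.10) where neighbouring 5′ LTRs had 0.28. The ES and Neuro2A levels also correlated more across 3′ than 5′ LTRs, with a rho of 0.81 against 0.33 over all pairs. In the large subfamilies this rho was 0.42 to 0.65 at 3′ LTRs, in each above that at 5′ LTRs (0.19 to 0.38). Unpaired loci had a rho of 0.34 to 0.69, and in IAPLTR1a_Mm theirs (0.69) exceeded that of 3′ LTRs (0.50). Whether shared reads or another property of sequence or mapping underlies the higher rho at 3′ than at 5′ LTRs was not tested. A loss of methylation at the 5′ promoter LTR of some copies in Neuro2A cells is a biological hypothesis that was not tested. A loss confined to Neuro2A cells would leave the ES contrast of IAPLTR1_Mm unexplained. A loss at 5′ LTRs alone would not describe the 63 pairs in which the 3′ end was lower by 20 points or more in Neuro2A cells.

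The lower level of Neuro2A cells at most loci does not rest on a few subfamilies, since the smallest median difference among the large subfamilies was 4.9 points (interval 4.6 to 5.2). Incomplete conversion of the ES library at one rate for every locus would shrink the unmethylated share to 0.64 of its value and hence the covariance of neighbouring loci to 0.41 of that in Neuro2A cells. The observed ratio of covariances was -0.0014 (interval -0.069 to 0.062), which argues against such a rate as the whole explanation. The interval draws pairs of neighbours as if independent, though pairs share loci, so it may be too narrow. The ES covariance itself was -0.044, against 30.6 in Neuro2A cells. The comparison also assumes that reads were shared between copies to a like degree in both libraries, which is unknown. A part of the 6.1-point shift that comes from conversion, from strain variants or from how single cultures were grown stays open, and so does the difference in cell type, which the design cannot separate from strain.

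The similarity of neighbouring loci in Neuro2A cells was not wholly accounted for by the clustering of subfamilies and LTR positions. The rho fell from 0.23 to 0.16 on relative levels and stayed above the highest shuffle of 0.076. The similarity was not confined to LTR pairs of one provirus either, with a rho of 0.17 for neighbours 10 kb to 1 Mb away (highest shuffle 0.073). A sequence property that shifts the level by as many points in both libraries would give equal covariances of neighbouring loci. It is argued against by the ratio of -0.0014 (interval -0.069 to 0.062, with pairs drawn as independent), if reads were shared between copies to a like degree in both libraries. Another sequence or mapping property shared by both libraries stays open. The ES rho was -0.0093 for the same neighbours, within the shuffles (-0.033 to 0.034), but ES levels did not correlate beyond shuffles even between the LTRs of a pair (rho 0.0086, shuffles -0.067 to 0.069), so a weaker effect in ES cells could have gone unseen. Regional loss of methylation in Neuro2A cells is a hypothesis consistent with these values, and structural or strain differences between the lines, which these tests do not address, remain open.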
